A study of Mus musculus with 22 samples.

How the data were processed

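Gene expression was measured on Illumina bead arrays in 22 samples of 4 mouse embryonic stem cell lines grown in serum-free N2B27 medium with LIF and 1 or 2 kinase inhibitors. PD is PD0325901, an inhibitor of MEK. SB is SB431542, an inhibitor of the type I receptors for TGF-beta, Activin and Nodal. CHIR is CHIR99021, an inhibitor of GSK3. R2i medium held PD and SB, 2i medium held PD and CHIR, and the other media held PD alone or SB alone. Lines B18 and B20 (C57BL/6) were derived in PD and SB and, per the labels, moved for 10 passages into the other media. They were measured on the 8-array MouseRef-8 platform with 3 R2i, 3 PD and 2 2i arrays per line (16 arrays). Lines B4 (C57BL/6) and C17 (BALB/c) were measured on the 6-array MouseWG-6 platform with 1 R2i, 1 PD and 1 SB array per line (6 arrays).

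The deposited probe profiles hold bead signal intensity per probe as exported from GenomeStudio, neither background-subtracted nor normalised. The same deposited files give a detection p-value per probe, which compares the signal with the negative control beads of the same array. The authors also deposited a table of normalised log2 values and a copy of it with identical values. The submitters' processing notes name GenomeStudio and limma without versions. The deposited log2 values differed from the values used here by a near constant (4.153 to 4.163 for B18 and B20, 4.141 to 4.151 for B4 and C17).

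Intensities were background-corrected against the negative controls and quantile normalised with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16, on each platform separately. A probe was kept when its detection p was below 0.01 on at least 2 arrays of its platform. Gene symbols were updated by gene identifier or transcript accession with the RefSeq table of assembly GRCm38.p6, which served for names only. For genes with several probes the probe with the highest mean was used, which left 9207 genes for B18 and B20 and 11003 for B4 and C17. B18 and B20 were fitted in limma with 1 mean for each of the 6 combinations of line and medium, and each contrast gave both lines equal weight. This left 10 residual degrees of freedom. B4 and C17 were fitted with medium and line as additive terms, which left 2. Moderated statistics came from eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene passed the test at an adjusted p below 0.05. A 2-fold call also needed an absolute log2 change of at least 1. Errors are moderated standard errors (SE).

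Where a gene was not detected on any array of a medium, its fold is given as a lower bound, with each array on which it was not detected set to at least the lowest signal of a detected probe on that array. P-values measure the spread between these arrays, which may be technical, because the labels do not say whether replicates were separate cultures. Each of B18 and B20 was on its own chip, so line and chip cannot be separated. Each medium took the same array positions on both chips, so medium and position cannot be separated either. The number of arrays limits the precision. For C17 in PD and C17 in SB one cell line field of the labels names B4 while the titles name C17. Of the 100 genes that best separated the R2i arrays of both lines, C17 PD was closer to C17 R2i for 90 and C17 SB for 96, against 7 for B4 PD and 26 for B4 SB, and the titles were used.

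Gene lists, comparisons, main tests and the rule for named genes were fixed before the data were examined. Tests of the B20 PD array that lay apart, the joint omission of B20 arrays and the tests of overlap were chosen later, as stated below. Named genes are the 8 largest rises and 8 largest falls among 2-fold calls with the same direction in both lines (predicted and clone names left out), up to 4 members of each described list that passed with the largest changes, the 5 largest differences between B18 and B20, and Nanog, Pou5f1, Sox2, Klf4, Esrrb, Zfp42, T, Axin2, Lefty1, Lefty2, Dusp6, Id1, Dnmt3b and Fgf5 where measured. The 23 lists tested cover naive pluripotency, general pluripotency, primed epiblast, primitive streak and mesoderm, definitive and primitive endoderm, neural ectoderm, trophoblast, feeder fibroblast, the 2-cell-like state, germline, canonical Wnt targets, MEK-ERK targets, Nodal-Activin-TGFb targets, BMP-SMAD1/5 targets, LIF-STAT3 targets, DNA methylation machinery, imprinted genes, glycolysis and hypoxia response, cholesterol synthesis, p53 targets, amino-acid and ER stress (ATF4), cell cycle, and epithelial and mesenchymal markers. Lists were tested with camera at its preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation.

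Data were simulated with the spread of each gene shrunk toward a common value and with 200 genes changed. In the B18 and B20 design all genes changed by 1 log2 unit passed the adjusted p, and so did 92.5% to 95.5% of genes changed by 0.5. Of those changed by 1, 46.3% to 49.3% met the 2-fold call. In the B4 and C17 design 98.5% to 100% of genes changed by 1 log2 unit passed and 26.9% to 49.3% of those changed by 0.5, and 37.3% to 50.8% of those changed by 1 met the 2-fold call. In either design 0 unchanged genes were called 2-fold, and 9 to 23 per comparison passed the adjusted p. Shrinking leaves out part of the range of spread across genes, and the adjusted p is harder to pass where fewer genes change. The shares recovered may thus be too high for B4 and C17, where 15 genes passed in R2i against PD. H19 rose there by 1.34 log2 units in B4 and 1.86 in C17 and was not called. Alternatives were other background corrections, normalisations, detection filters, probe choices, variance models, array weights, terms for line, sets of arrays and set tests, and leaving out each array in turn.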

Results

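Transcript levels were measured in 22 arrays of 4 mouse embryonic stem cell lines kept in N2B27 medium with LIF and different inhibitors. B18 and B20 gave 16 arrays: 3 in R2i, 3 in PD and 2 in 2i for each line. B4 and C17 gave 6 arrays: 1 in R2i, 1 in PD and 1 in SB for each line, so that the line was the only replicate. Between 10822 and 11670 probes (42.1% to 45.4%) were detected per B18 or B20 array, and between 13591 and 14366 (30.0% to 31.7%) per B4 or C17 array. The upper quartile of raw signal was 1.99 to 2.41 times the mean of the negative controls in the first set and 1.32 to 1.38 times in the second. Replicate arrays of B18 and B20 correlated with one another across genes at 0.990 to 0.996, where genes are not independent replicates. In B4 and C17, the first principal component held 54.9% of the variance and parted the lines, and the second held 24.9% and set the SB arrays apart.

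The comparison of R2i with PD in B18 and B20 sets cells with PD and SB against cells with PD alone. R2i was the medium of derivation of both lines, and the PD cells had been moved out of it. An effect of SB therefore cannot be told apart from one of the move. The Nodal feedback inhibitors Lefty1 and Lefty2 were detected on all 6 PD arrays and on none of the 6 R2i arrays. Lefty2 was at least 19.2-fold lower (adjusted p = 1.7e-11) and Lefty1 at least 15.95-fold lower (adjusted p = 1.0e-13) in R2i. The germ cell homeobox gene Rhox5 rose by 2.75 log2 units (SE 0.12), the naive-state and germ cell gene Dppa3 (Stella) by 2.11 (SE 0.12), and the BMP target Id1 by 2.06 (SE 0.27). Rhox5, Dppa3 and Id1 were each higher in both lines, though Id1 ranged from 6.52 to 9.01 among the B20 R2i arrays.

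Of 9207 genes, 66 met the 2-fold call in B18 and B20 (21 higher and 45 lower in R2i), each with the same direction in both lines, and 1732 passed the adjusted p at any fold. B18 alone gave 117 such calls (44 higher, 73 lower) and B20 alone 77 (23 higher, 54 lower). Without background correction 18 of the 66 were called. Id1, H19 and Hormad2 were detected on 3 of 6 PD arrays and Spink1 on 3 of 6 R2i arrays, so their changes rest in part on background. So do those of Dppa3, not detected on B18 PD replicates 1 and 3 (4.91 and 4.76). The same holds for Rhox5, not detected on B20 PD replicates 1 and 2 (4.65 and 5.02). Among the largest falls were Trh, which encodes thyrotropin-releasing hormone (log2 change -3.10, SE 0.12), the coatomer subunit gene Copz2 (-3.05, SE 0.26), the keratin gene Krt17 (-2.09, SE 0.14), Dpysl4 (-1.85, SE 0.13) and Spink1 (-1.79, SE 0.16). Among the largest rises were the peptidase gene Dpp4 (2.19, SE 0.17), the meiotic gene Hormad2 (1.73, SE 0.08), the imprinted RNA H19 (2.83-fold), Bcas1 (1.38, SE 0.13) and the ETS-family gene Spic (1.35, SE 0.10). On the third B20 PD array Lefty2, Copz2 and Dpp4 lay between the levels of the other B20 PD arrays and those of R2i (Copz2 8.43 against 9.98 and 10.15 in the other B20 PD arrays).

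**Figure D1:**
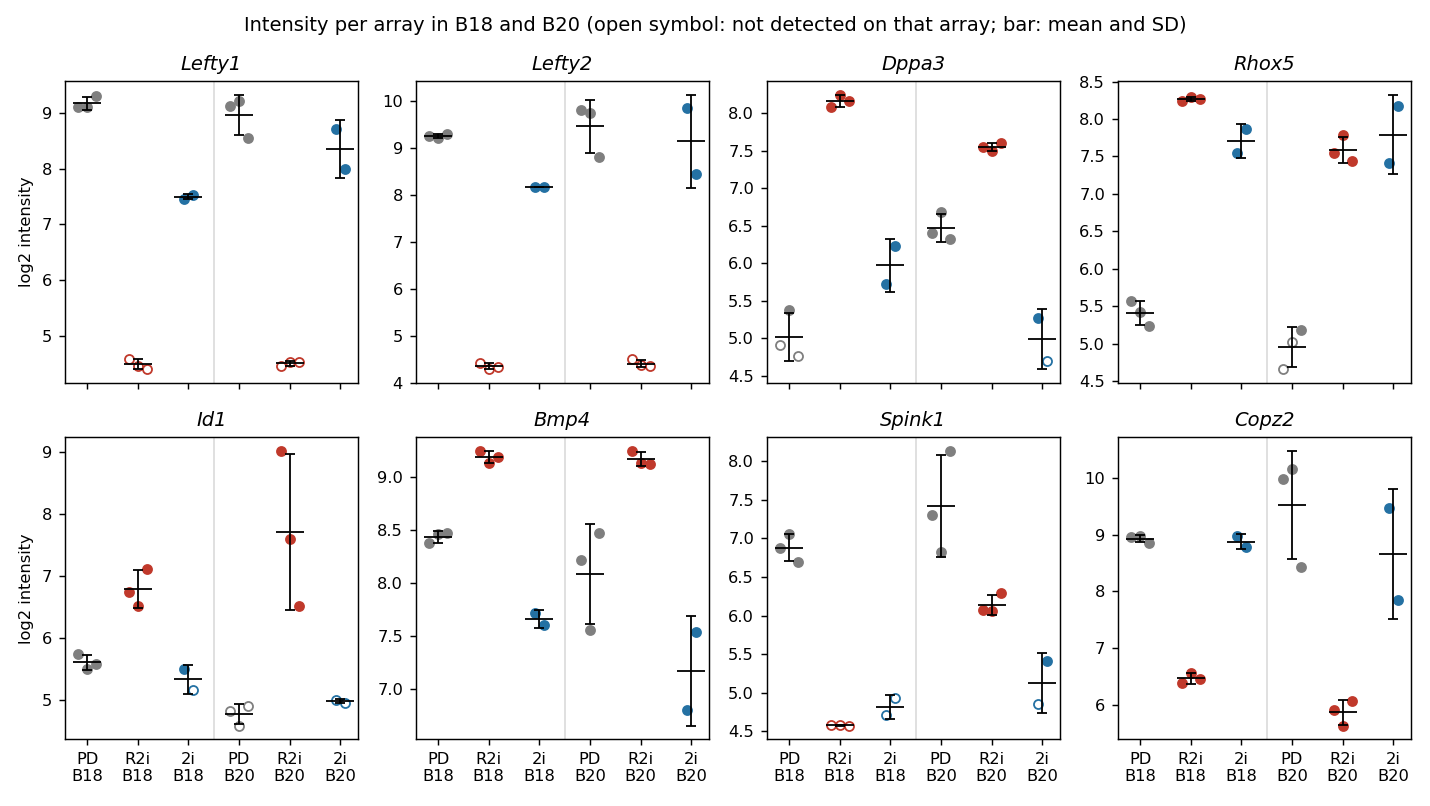
Log2 intensity (vertical axis) of 8 genes on each B18 and B20 array, grouped by medium and line, with the mean and standard deviation of each group of 2 or 3 arrays; open symbols mark arrays on which the gene was not detected. Lefty1 and Lefty2 were not detected on any R2i array, while Rhox5 was higher in R2i and 2i than in PD in both lines.

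Targets of Nodal, Activin and TGF-beta fell as a group in R2i against PD. Of 17 measured, 10 fell, 1 rose and 6 did not pass, with the same 10 and 1 adjusted over the list alone. Camera gave an adjusted p of 3.2e-06, and an adjusted p = 0.076 with an estimated correlation. Beside the Lefty genes, the Nodal co-receptor gene Tdgf1 fell by 0.92 log2 units. The list that rose most was that of the germline: 10 of 16 measured genes rose and 0 fell (counts that were the same adjusted over the list alone), with an adjusted p of 5.3e-06, and an adjusted p = 0.076 with an estimated correlation. Its members included Taf7l (detected on 6 of 6 R2i arrays and 1 of 6 PD arrays), Fkbp6 (1.14, SE 0.11) and Xlr4a, which was not detected in PD and was at least 1.28-fold higher.

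Imprinted genes rose too, 8 of 15 measured with 0 falling (the same adjusted over the list alone, adjusted p = 5.2e-05, and adjusted p = 0.076 with an estimated correlation). Examples were H19, the growth inhibitor gene Cdkn1c (1.00, SE 0.08) and Grb10, whose mean change of 0.85 joined 1.86 in B18 with -0.16 in B20 (difference -2.01, adjusted p = 1.5e-06). Endoderm markers went down: 7 of 13 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.0094, and adjusted p = 0.14 with an estimated correlation), among them the transcription factor gene Sox7 (-1.16, SE 0.08) and the basement membrane collagen gene Col4a1 (-0.80, SE 0.10). Trophoblast markers moved both ways, with 5 of 12 higher and 3 lower (6 and 3 adjusted over the list alone, adjusted p = 0.045 for a rise, and adjusted p = 0.25 with an estimated correlation). The risers included H19 and the transcription factor genes Gata3 (detected on 6 of 6 R2i arrays and 1 of 6 PD arrays) and Tfap2c (0.62), while Tead4 fell by 0.44 log2 units.

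The core pluripotency genes moved little between R2i and PD. Pou5f1 (-0.13, adjusted p = 0.12), Sox2 (-0.14, 0.23), Klf4 (-0.17, 0.083), Esrrb (-0.06, 0.54) and Zfp42 (0.08, 0.58) did not pass. Nanog was 0.23 log2 units lower at an adjusted p of 0.044, and left the threshold when any of several single arrays was left out (adjusted p = 0.11 without B20 PD replicate 2 or B18 PD replicate 3). The general pluripotency list had 5 of 14 genes lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.041, and adjusted p = 0.14 with an estimated correlation), with Tdgf1 among the falls. LIF-STAT3 targets had 6 of 18 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.19 with an estimated correlation), with Icam1 at -0.56, Pim3 at -0.55 and Bcl3 at -0.51. In the naive list 10 of 22 genes were lower and 3 higher (11 and 4 adjusted over the list alone). Its mean change of 0.01 and median of -0.12 differed in sign and its camera test pointed down without a call (adjusted p = 0.15). Dppa3 and Spic stood at its upper end, and Dppa5a (-0.55) and Jam2 (-0.52) at its lower end.

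BMP-SMAD1/5 targets split, with 4 of 11 higher and 3 lower (4 and 4 adjusted over the list alone) and no call (adjusted p = 1.00, where the test pointed down while mean and median were above 0). Id1 and the ligand gene Bmp4 (0.92, SE 0.13) rose, while Id4 (-1.21, SE 0.09) and the Notch and BMP target Hey1 (-0.89, SE 0.07) fell. In the DNA methylation machinery 3 of 11 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.17). The de novo methyltransferase gene Dnmt3b rose by 0.73 log2 units (SE 0.07) and the deaminase gene Apobec1 by 0.55, and Prdm14 fell by 0.52. Among primed epiblast genes 4 of 10 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.35), with Otx2 at -1.21 (SE 0.07). Primitive streak genes had 3 of 7 lower and 0 higher (the same adjusted over the list alone, adjusted p = 0.076), with Fgf17 2.83-fold lower. MEK-ERK targets had 3 of 20 lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.32), and Dusp6 did not pass (-0.17, adjusted p = 0.24). Canonical Wnt targets had 2 of 10 lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.41), with Notum at -0.93 and Axin2 at 0.04 (adjusted p = 0.84). Fgf5 and T were not among the genes that passed the detection filter.

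The comparison of R2i with 2i asks how the media differ when the partner of the MEK inhibitor is SB in one and CHIR in the other. Here too, only the 2i cells had been moved out of the medium of derivation. Lefty2 was at least 11.9-fold lower and Lefty1 at least 7.21-fold lower in R2i than in 2i, and both were detected on all 4 2i arrays. The BMP targets Id1 and Id2 were higher in R2i by 2.09 (SE 0.30) and 1.90 (SE 0.17) log2 units and the ligand gene Bmp4 by 1.76 (SE 0.15), while the BMP-SMAD1/5 list as a whole split (5 of 11 higher, 4 lower, adjusted p = 0.40). Dppa3 was higher by 2.38 (SE 0.13), and the matricellular genes Ccn1 and Ccn2 by 2.10 (SE 0.23) and 1.44 (SE 0.16). Of 18 genes of cholesterol synthesis 11 were lower in R2i, a list call that was lost with an estimated correlation (adjusted p = 0.12). Axin2, a direct Wnt target, was lower by 0.65 log2 units (SE 0.11, adjusted p = 4.3e-04).

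In all, 114 genes met the 2-fold call (41 higher and 73 lower in R2i), all with the same direction in both lines, and 2539 passed at any fold. B18 alone gave 153 (71 higher, 82 lower) and B20 alone 145 (44 higher, 101 lower). Changes rest in part on background for Dclk3, Nt5e and Adh1, detected on 1, 2 and 3 of 6 R2i arrays, and for Id1 and Peg3, each detected on 1 of 4 2i arrays. Dppa3 was not detected on B20 2i replicate 2. Without background correction 26 of the 114 were called, and 72 among genes detected on every array. With median scaling the balance in B18 turned to 93 higher and 57 lower. Further falls were Trh (-3.11, SE 0.14), Copz2 (-2.59, SE 0.29), Dclk3 (-2.23, SE 0.12), the ectonucleotidase gene Nt5e (-2.16, SE 0.19), the alcohol dehydrogenase gene Adh1 (3.99-fold) and Vwf, which encodes von Willebrand factor (-1.88, SE 0.12). Further rises were Wdr45 (1.82, SE 0.09), H19 (not detected in 2i, at least 2.93-fold higher) and the acyltransferase gene Gpat3 (not detected in 2i, at least 2.28-fold higher).

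Of 18 cholesterol synthesis genes measured, 11 fell and 0 rose (13 and 0 adjusted over the list alone, adjusted p = 4.6e-07, and adjusted p = 0.12 with an estimated correlation). The largest falls were those of Cyp51 (-0.86, SE 0.08), Dhcr7 (-0.63, SE 0.12) and Stard4 (-0.61, SE 0.12). Glycolysis and hypoxia response genes fell as well, 12 of 22 with 2 higher (14 and 2 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.33 with an estimated correlation), from Egln3 (-1.22, SE 0.08) and Aldoc (-0.96, SE 0.10) to Ndrg1, which rose (1.23, SE 0.09). Imprinted genes had 8 of 15 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.12 with an estimated correlation), with Cdkn1c at 1.39 (SE 0.09), Peg3 at 0.80 and Igf2 at 0.69. Trophoblast markers had 5 of 12 higher and 0 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0096, and adjusted p = 0.25 with an estimated correlation), led by H19 and Gata3, which was not detected in 2i (at least 1.21-fold higher). Genes of the amino-acid and ER stress response had 9 of 25 higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.0096, and adjusted p = 0.51 with an estimated correlation), with Cebpb at 1.06 (SE 0.09), Trib3 at 0.75 and Atf5 at 0.68.

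The remaining lists were not called in R2i against 2i. The counts of BMP-SMAD1/5 targets given above were the same adjusted over the list alone. Nodal-Activin-TGFb targets had 5 of 17 lower and 4 higher (7 and 5 adjusted over the list alone, adjusted p = 0.22), since Ccn1 and Ccn2 rose while the Lefty genes fell. Canonical Wnt targets had 3 of 10 lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.41), with Notum at -0.76 (SE 0.09) beside Axin2. In the DNA methylation machinery 4 of 11 were higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.13), with Dnmt3b at 0.65 (SE 0.07), Dnmt3l at 0.48 and Dnmt1 at -0.36. Among p53 targets 7 of 19 were higher and 4 lower (the same adjusted over the list alone, adjusted p = 0.27), with Bbc3 (Puma) at 1.07 (SE 0.09) and Pmaip1 (Noxa) at -0.96 (SE 0.12). Epithelial and mesenchymal markers had 4 of 16 higher and 1 lower (7 and 4 adjusted over the list alone, adjusted p = 0.19), with Esrp1 at 1.02 (SE 0.07). In the germline list, 6 of 16 genes were lower and 5 higher (6 and 6 adjusted over the list alone, adjusted p = 0.58), where mean (-0.12) and median (0.05) differed in sign and the test pointed down, and Fkbp6 (-1.75, SE 0.12) and Xlr4a (-1.15) stood apart from Rhox6 (0.87). Cell cycle genes had 8 of 26 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.21), with Cdc20 at 0.87 (SE 0.07). Feeder fibroblast genes had 0 of 5 higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.63), and genes of the 2-cell-like state 1 of 3 higher and 1 lower (1 and 2 adjusted over the list alone, adjusted p = 0.41). Nanog (0.13), Pou5f1 (-0.04), Sox2 (-0.09), Klf4 (0.17), Esrrb (-0.04), Zfp42 (-0.12) and Dusp6 (0.18) did not pass.

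**Figure D2:**
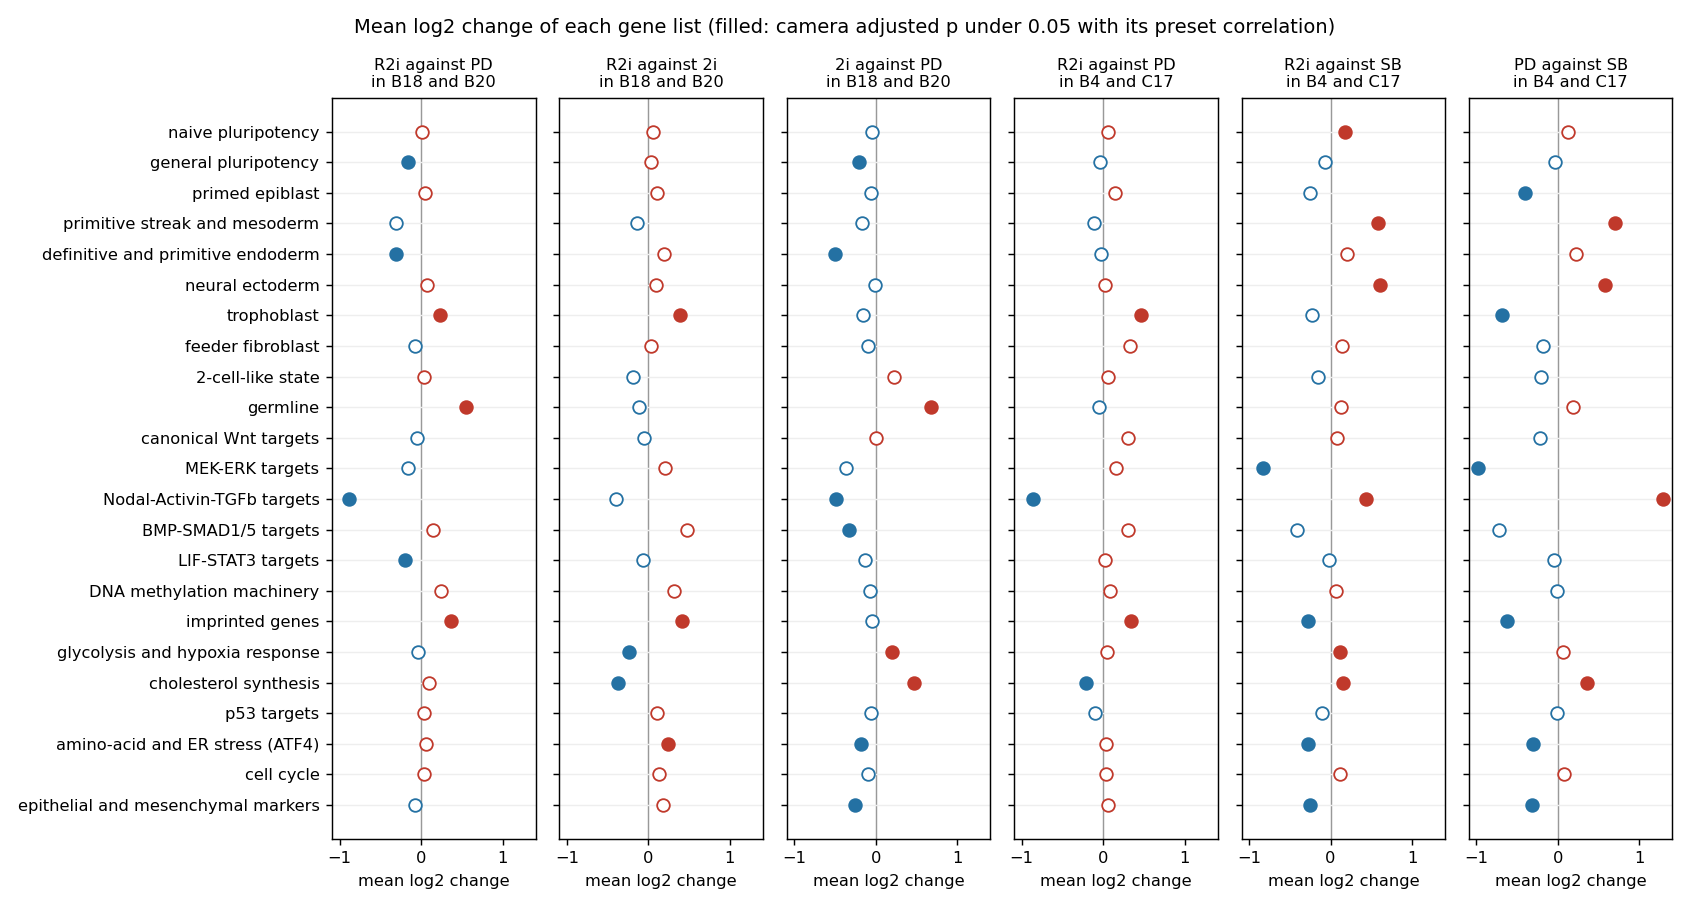
Mean log2 change (horizontal axis) of the measured members of each gene list in 6 comparisons, red above 0 and blue below; filled symbols have a camera adjusted p below 0.05 with the preset correlation. The mean of Nodal-Activin-TGFb targets is below 0 in R2i against PD on both platforms and that of MEK-ERK targets is below 0 in R2i and PD against SB, calls that were lost with an estimated correlation (adjusted p = 0.076, 0.76, 0.44 and 0.37).

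The comparison of 2i with PD sets cells with PD and CHIR against cells with PD alone, both moved out of R2i. Cholesterol synthesis genes rose together in 2i, 15 of 18 measured with 0 lower (the same adjusted over the list alone, adjusted p = 9.8e-11). This was the only list in any of the 6 comparisons whose call was kept with an estimated correlation (adjusted p = 0.042 with an estimated correlation). Dhcr7, which makes the last step to cholesterol, rose by 0.98 log2 units (SE 0.12), and Cyp51 and Stard4 by 0.82 each (SE 0.08 and 0.12). The germline genes with the largest rises were Fkbp6 (2.89, SE 0.12), Rhox5 (2.57, SE 0.13) and Xlr4a, which was not detected in PD and was at least 2.85-fold higher in 2i. Axin2 rose by 0.68 (SE 0.11, adjusted p = 3.5e-04).

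A 2-fold call was met by 77 genes (43 higher and 34 lower in 2i), each with the same direction in both lines, and 2176 passed at any fold. B18 alone gave 121 (55 higher, 66 lower) and B20 alone 106 (68 higher, 38 lower). Changes rest in part on background for Spink1 and Dok2, detected on 1 and 2 of 4 2i arrays, and for Adh1, Nt5e and Fthl17f, detected on 3 of 6 PD arrays. That of Rhox5 does too, since it was not detected on B20 PD replicates 1 and 2. Without background correction 15 of the 77 were called, and 40 among genes detected on every array. With median scaling in place of quantile normalisation the 2-fold calls were 38 higher and 46 lower, of which 72 were shared, and the median change of all genes in B18 moved by -0.14 log2 units. The largest rises also held the peroxidase gene Gpx2 (2.16, SE 0.08), Adh1 (2.03, SE 0.14), the protease gene Ctsc (1.78, SE 0.07), Nt5e (1.77, SE 0.19) and the X-linked gene Fthl17f (1.72, SE 0.10). The largest falls were Spink1 (-2.17, SE 0.18), Dpysl4 (-2.04, SE 0.14), Ccn1 (-1.88, SE 0.23), Wdr45 (-1.86, SE 0.09), Dok2 (-1.86, SE 0.07), Sox7 (-1.86, SE 0.09), Id2 (-1.83, SE 0.17) and the transcription factor gene Msc (-1.77, SE 0.09).

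Besides cholesterol synthesis, 8 lists were called in 2i against PD. In the germline list 10 of 16 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 3.1e-05, and adjusted p = 0.084 with an estimated correlation). Of 17 Nodal-Activin-TGFb targets 9 fell and 0 rose (the same adjusted over the list alone, adjusted p = 8.8e-05, and adjusted p = 0.094 with an estimated correlation), with Ccn2 (-1.32, SE 0.16) and Lefty1 (-1.15, SE 0.13). Lefty2 was 0.70 lower (SE 0.21, adjusted p = 0.023) and left the threshold without B20 2i replicate 2 (-0.34, adjusted p = 0.15), without either B18 2i array (0.056 and 0.061) and without B20 PD replicate 1 or 2 (0.056 and 0.052). Endoderm markers had 5 of 13 lower and 1 higher (5 and 2 adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.094 with an estimated correlation), with Col4a1 at -1.62 (SE 0.11) and Col4a2 at -1.39 (SE 0.15). Glycolysis genes had 12 of 22 higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.0037, and adjusted p = 0.24 with an estimated correlation), with Aldoc at 0.85, Pfkm at 0.72 and Pfkp at 0.65. General pluripotency genes had 7 of 14 lower and 0 higher (the same adjusted over the list alone, adjusted p = 0.0044, and adjusted p = 0.084 with an estimated correlation), such as Gdf3 (-0.46) and Zscan10 (-0.42).

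Epithelial and mesenchymal markers had 7 of 16 lower and 0 higher in 2i against PD (the same adjusted over the list alone, adjusted p = 0.0044, and adjusted p = 0.094 with an estimated correlation), with S100a6 at -1.07 (SE 0.13) and Krt8 at -0.77. Amino-acid and ER stress genes had 7 of 25 lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.45 with an estimated correlation), with Cebpb at -0.72. BMP-SMAD1/5 targets had 5 of 11 lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.035, and adjusted p = 0.24 with an estimated correlation), with Id2, Bmp4 (-0.84, SE 0.15) and Hey1 (-0.59). Canonical Wnt targets as a list were not called: 3 of 10 were lower and 2 higher (the same adjusted over the list alone, adjusted p = 0.75), with a mean of 0.01, a median of -0.11 and a test that pointed down. MEK-ERK targets had 9 of 20 lower and 3 higher (11 and 3 adjusted over the list alone, adjusted p = 0.12). The immediate early genes among them varied widely between arrays of 1 medium, as Fosb did from 5.36 to 8.63 among the B20 PD arrays, and the calls of Fosb (-1.65, adjusted p = 0.030) and Egr1 (-1.12, adjusted p = 0.049) ended without B18 2i replicate 1 (adjusted p = 0.14 and 0.19), B20 2i replicate 1 (0.090 for Fosb, and 0.25 with a change of -0.74 for Egr1) and several other single arrays. Nanog fell by 0.36 (SE 0.08, adjusted p = 0.0048) and Klf4 by 0.34 (SE 0.07, adjusted p = 0.0029), while Pou5f1 (-0.09), Sox2 (-0.04), Esrrb (-0.02) and Zfp42 (0.20) did not pass.

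The B4 and C17 arrays compare R2i with PD in another pair of lines, whose time in each medium the labels do not give. Lefty1 (log2 change -4.54, SE 0.65), Lefty2 (-4.25, SE 0.61) and Copz2 (-2.35, SE 0.20) were again among the genes with the largest falls in R2i. Lefty1 and Lefty2 were not detected in R2i in C17, so their mean changes rest in part on signal near background. They were detected in R2i in B4, where their changes from PD were -2.69 and -2.48. Krt17 (-1.49, SE 0.16) fell as well, and the SoxB gene Sox21 rose (1.32, SE 0.15). In all, 14 genes met the 2-fold call (3 higher and 11 lower), 15 passed at any fold and 992 of 11003 had an unadjusted p below 0.05. With no detection filter, and with no line term, limma made 0 calls. The count was 5 without C17 R2i and 46 without B4 R2i, and Sox21 and Krt17 left the threshold without C17 R2i (adjusted p = 0.13 and 0.098).

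Of 15 Nodal-Activin-TGFb targets 3 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 0.0042). Trophoblast markers had 0 of 12 past the test in limma (6 higher and 1 lower adjusted over the list alone) and a call for a rise (adjusted p = 4.7e-04). Imprinted genes had 0 of 16 past the test in limma (5 higher and 0 lower adjusted over the list alone) and a call for a rise (adjusted p = 0.0014). Cholesterol synthesis genes had 0 of 20 past the test in limma, also adjusted over the list alone, and a call for a fall (adjusted p = 0.0014). For each of these 4 lists the adjusted p = 0.76 with an estimated correlation. No member of the germline list, which rose in B18 and B20, passed the test in limma. Its member Rhox5 changed by 0.53 in B4 and 0.45 in C17, and Fkbp6 by 0.071 and -0.215. Id1 (0.69, adjusted p = 0.78) and Dnmt3b (0.55, adjusted p = 0.30) did not pass, and neither did Nanog (-0.05), Pou5f1 (0.00), Sox2 (-0.19), Klf4 (0.07), Esrrb (0.04) or Zfp42 (0.12).

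Across the 8038 genes tested on both platforms, the change from PD to R2i in B18 and B20 correlated with that in B4 and C17 (Pearson r = 0.483, Spearman rho = 0.266, across genes, which are not independent replicates). Of the 59 shared genes called 2-fold in B18 and B20, 54 (91.5%) had the same sign in B4 and C17, against 58.1% of all genes. Lefty1, Lefty2, Copz2 and Krt17 were among 9 genes called lower in both sets, where independent lists would share 0.0534. The only gene called higher in both sets carries a clone-like name, AA467197 (named after its values were seen), where independent lists would share 0.00746. No gene was called in opposite directions. In each of the 4 lines 13 of the 59 genes were higher and 37 were lower in R2i.

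**Figure D3:**
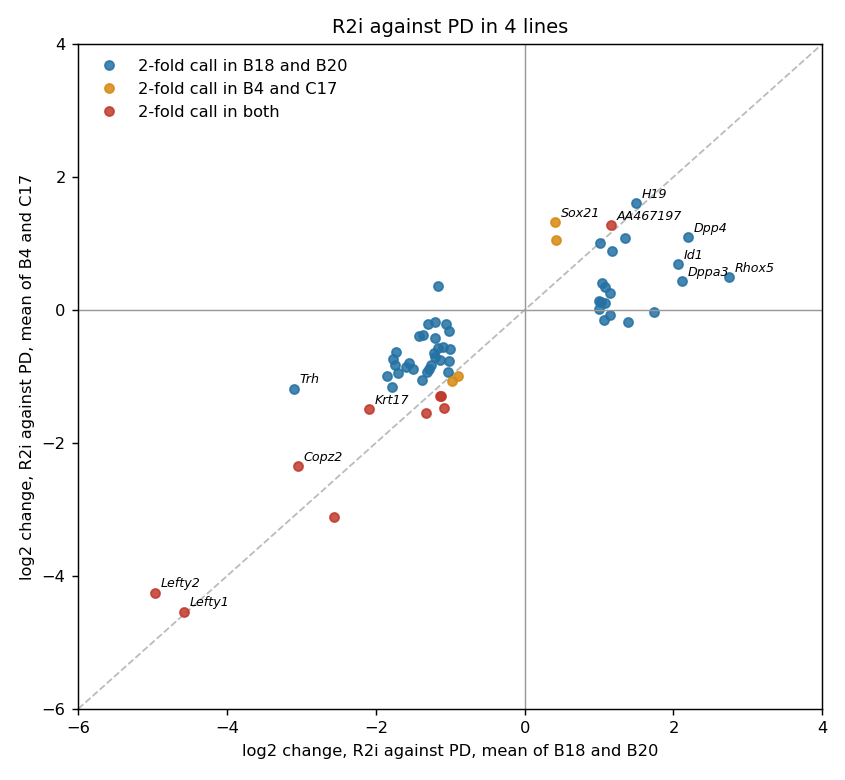
Log2 change of R2i against PD for the genes called 2-fold in either set of lines, mean of B18 and B20 (horizontal axis) against mean of B4 and C17 (vertical axis), with a dashed line of equal change. Lefty1, Lefty2 and Copz2 lie at the lower left, where the changes of Lefty1 and Lefty2 are limited by background since neither was detected in R2i except in B4.

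R2i against SB in B4 and C17 sets a medium with the MEK inhibitor against one without it, both with SB. Of 18 MEK-ERK targets 7 fell in R2i and 11 did not pass, a list call that was lost with an estimated correlation (adjusted p = 0.44). The immediate early gene Egr1 was 10.97-fold lower (adjusted p = 0.0027), and log2 changes were -2.38 (SE 0.15) for the phosphatase gene Dusp4, -1.63 (SE 0.19) for Dusp6, -2.38 (SE 0.38) for the ETS gene Etv4 and -1.67 (SE 0.21) for the feedback inhibitor gene Spry4. The iron exporter gene Slc40a1 was not detected in R2i and was at least 4.72-fold lower. Among the rises were the organizer gene Gsc (1.61, SE 0.18), the neural adhesion gene Ncam1 (1.60, SE 0.22), the imprinted deiodinase gene Dio3 (1.62, SE 0.24), Cdhr1 (1.96, SE 0.21), Ccno (1.69, SE 0.26) and the autophagy receptor gene Calcoco2 (2.55, SE 0.42), whose older name Ndp52 a second probe carries (2.27, SE 0.32). Spry4 was detected on 1 of 2 R2i arrays, and Gsc, Ncam1, Dio3, Cdhr1 and Ccno on 1 of 2 SB arrays, so their changes rest in part on background. Other falls were Snai3 (-1.83, SE 0.18) and Ap1m2 (-1.53, SE 0.15).

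The 2-fold call was met by 92 genes (45 higher and 47 lower in R2i), and 242 passed at any fold. With no detection filter, and with no line term, limma made 0 calls (1888 genes had an unadjusted p below 0.05 with both in place). The count was 46 without C17 R2i, where Etv4 (adjusted p = 0.080), Calcoco2 (0.092) and Ncam1 (0.061) left the threshold, and 234 without B4 SB. Of 18 MEK-ERK targets 7 fell and 0 rose (8 and 1 adjusted over the list alone, adjusted p = 6.8e-06). Neural markers had 1 of 5 higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.0017), and primitive streak genes 1 of 4 higher and 0 lower (2 and 0 adjusted over the list alone, adjusted p = 0.017). Amino-acid and ER stress genes had 2 of 22 lower and 0 higher (3 and 0 adjusted over the list alone, adjusted p = 0.0017), epithelial and mesenchymal markers 2 of 17 lower and 1 higher (8 and 2 adjusted over the list alone, adjusted p = 0.0060), and imprinted genes 1 of 16 lower and 0 higher (4 and 1 adjusted over the list alone, adjusted p = 0.017). Nodal-Activin-TGFb targets had 1 of 15 higher (the same adjusted over the list alone, adjusted p = 0.048), naive pluripotency genes 2 of 22 higher and 0 lower (3 and 1 adjusted over the list alone, adjusted p = 0.049), and glycolysis genes 1 of 21 higher and 1 lower (2 and 2 adjusted over the list alone, adjusted p = 0.049). The gene that passed in the Nodal-Activin-TGFb list and the one in the primitive streak list were the same, Gsc. Cholesterol synthesis genes had 0 of 20 past the test in limma, also adjusted over the list alone, with a call for a rise (adjusted p = 0.049, and adjusted p = 0.56 with an estimated correlation). Each of the other lists called had an adjusted p = 0.44 with an estimated correlation.

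Spic, in the naive list, rose by 1.62 log2 units in R2i against SB (SE 0.30) and left the threshold without C17 R2i (1.03, adjusted p = 0.14) or C17 SB (0.94, adjusted p = 0.080). Id1 was 2.48 log2 units below its level in SB and did not pass (adjusted p = 0.060). Lefty1 and Lefty2, which were not detected in SB, did not pass (adjusted p = 0.26 and 0.19). Nanog (0.52, adjusted p = 0.19), Pou5f1 (0.02), Sox2 (-0.17), Klf4 (0.10), Esrrb (-0.01) and Zfp42 (0.17) did not pass either.

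PD against SB in B4 and C17 sets the MEK inhibitor against the receptor inhibitor, each alone. Of 15 Nodal-Activin-TGFb targets 5 were higher in PD, and of 18 MEK-ERK targets 8 were lower and 1 higher, list calls that were lost with an estimated correlation (adjusted p = 0.37 for both). Lefty1 was at least 46.2-fold and Lefty2 at least 38.3-fold higher in PD, and neither was detected in SB. Copz2 (3.19, SE 0.20), Dpysl4 (2.59, SE 0.16), the Hedgehog effector gene Gli2 (2.04, SE 0.18) and the chemokine gene Ccl25 (2.12, SE 0.31) were higher in PD as well. Egr1 (-4.63, SE 0.33), Dusp4 (-3.19, SE 0.15), Etv4 (-2.69, SE 0.38) and Dusp6 (-2.14, SE 0.19) were lower in PD, and so were Bmp4 (-3.34, SE 0.39), Id1 (-3.17, SE 0.58) and Id3 (-1.73, SE 0.16). Egr1, Etv4, Id3, H19 and Grhl2 were detected on 1 of 2 PD arrays, and Copz2, Gsc and Ncam1 on 1 of 2 SB arrays, so their changes rest in part on background.

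**Figure D4:**
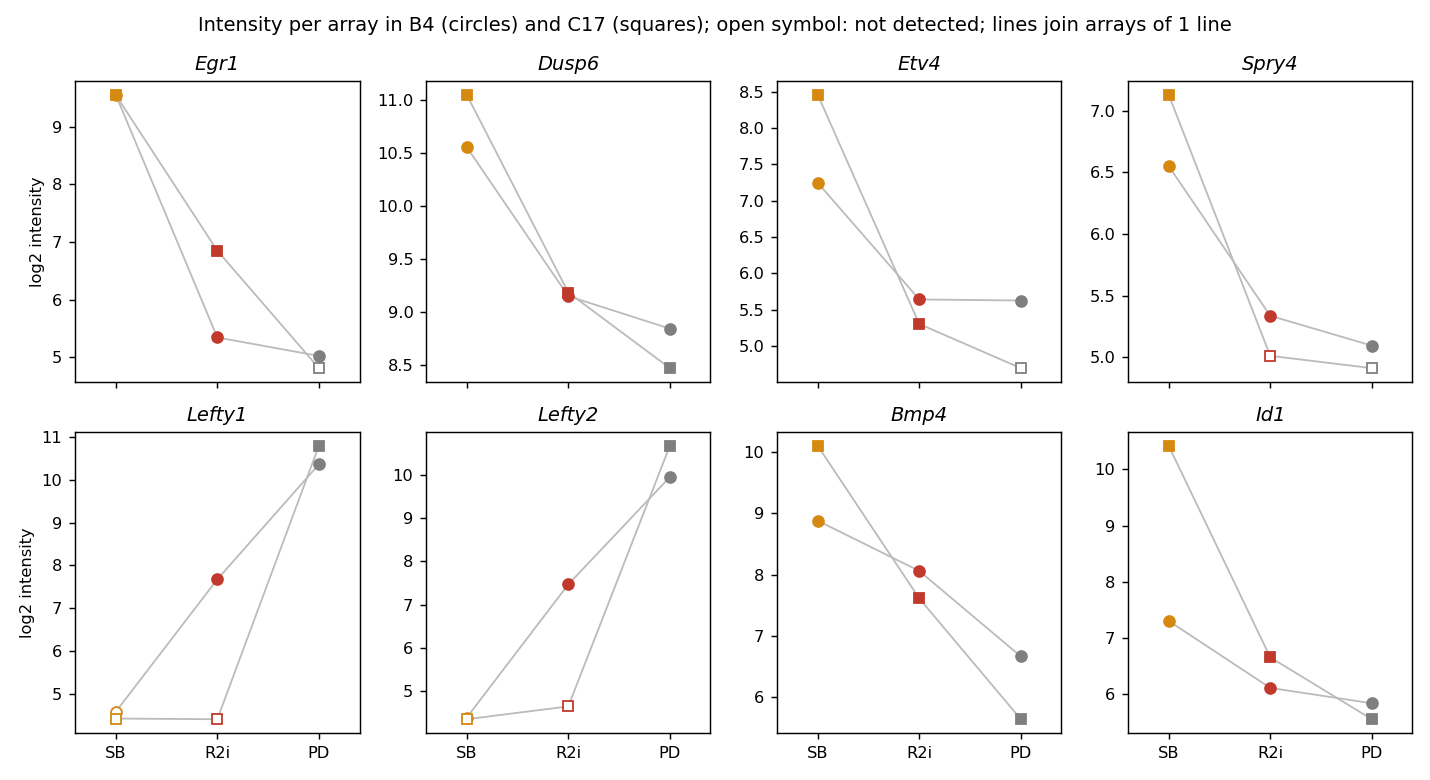
Log2 intensity (vertical axis) of 8 genes on the 6 arrays of B4 (circles) and C17 (squares) in SB, R2i and PD; lines join arrays of a line and open symbols mark arrays on which the gene was not detected. Egr1 and Dusp6 are highest in SB, and Lefty1 and Lefty2 are highest in PD in both lines.

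A total of 172 genes met the 2-fold call in PD against SB (97 higher and 75 lower in PD), and 576 passed at any fold. With no detection filter 2 genes were called, and with no line term 3. The count was 143 without C17 PD and 283 without B4 SB. Nodal-Activin-TGFb targets had 5 of 15 higher and 0 lower (8 and 1 adjusted over the list alone, adjusted p = 8.4e-05), with Gsc at 1.43 (SE 0.18). MEK-ERK targets had 8 of 18 lower and 1 higher (9 and 4 adjusted over the list alone, adjusted p = 1.5e-05). Imprinted genes had 4 of 16 lower and 0 higher (9 and 1 adjusted over the list alone, adjusted p = 2.0e-06), with H19 at -2.05 (SE 0.33) and Igf2 at -1.92 (SE 0.24). Trophoblast markers had 5 of 12 lower and 0 higher (6 and 0 adjusted over the list alone, adjusted p = 3.2e-05), with Krt8 at -1.34 and Krt18 at -1.14. Primed epiblast genes had 4 of 11 lower and 1 higher (6 and 2 adjusted over the list alone, adjusted p = 0.0097), with Grhl2 at -1.61 and Cldn6 at -1.15. Neural markers had 2 of 5 higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.0067), with Ncam1 at 1.77 (SE 0.22). For each of these 6 lists the adjusted p = 0.37 with an estimated correlation. The falls of H19, Igf2 and Peg10 count in both the imprinted and the trophoblast list. Those of Krt8 and Krt18 count in the trophoblast list and again among the epithelial and mesenchymal markers below.

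Cholesterol synthesis genes had 2 of 20 higher and 0 lower in PD against SB (7 and 0 adjusted over the list alone, adjusted p = 1.5e-05, and adjusted p = 0.39 with an estimated correlation). Amino-acid and ER stress genes had 4 of 22 lower and 0 higher (8 and 2 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.46 with an estimated correlation), with Ddit3 at -1.33. Epithelial and mesenchymal markers had 6 of 17 lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p = 0.0062, and adjusted p = 0.38 with an estimated correlation), with S100a6 at -1.80 and Vim at 1.37. Primitive streak genes had 2 of 4 higher and 0 lower (the same adjusted over the list alone, adjusted p = 0.0071, and adjusted p = 0.39 with an estimated correlation), with Fgf17 at 1.42 (SE 0.16). BMP-SMAD1/5 targets had 3 of 9 lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.48), with a mean of -0.72, a median of 0.17 and a test that pointed down. Nanog (0.57, adjusted p = 0.13), Pou5f1 (0.02), Sox2 (0.01), Klf4 (0.03), Esrrb (-0.05) and Zfp42 (0.05) did not pass.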

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

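For the B20 PD array that lay apart, all tests were chosen after its values were seen, and so was leaving out B20 PD replicate 3 together with B20 2i replicate 2. B20 2i replicate 2 was nearer to B20 R2i than replicate 1 was for Lefty2 (8.43 against 9.83), Copz2 (7.85 against 9.47) and Dpp4 (7.02 against 6.08), which enters all B20 2i results. The share of R2i material that B20 2i replicate 2 would need was 38.1% from genes lower in R2i (31.7% to 43.7%) and 20.6% from genes higher (15.9% to 28.6%). These intervals do not overlap. Its shares of the log2 change to R2i were 27.4% (22.9% to 31.9%) and 30.9% (24.3% to 40.1%), which overlap. For B20 PD replicate 3, given below, the mixing shares overlapped and the log2 shares did not. For B20 2i replicate 2, both the genes and the reference came from replicate 1 alone. Noise in replicate 1 can then make replicate 2 look nearer to R2i. No share was computed for replicate 1, so the shares of replicate 2 do not decide whether it lay apart. With 2 arrays the number of genes 2-fold apart, 19, is the same for both 2i arrays. A test of the difference between the lines marked each result here: how far the effect of a medium in B20 departed from that in B18. For R2i against PD 65 genes differed by 2-fold or more, for 2i against PD 50 and for R2i against 2i 32. Leaving out single arrays moved these counts from 54 (without B20 PD replicate 1) to 122 (without B20 PD replicate 3), from 29 (without B18 2i replicate 2) to 95 (without B20 PD replicate 3), and from 13 (without B20 2i replicate 1) to 83 (without B20 2i replicate 2).

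Dppa3, a gene of naive cells and germ cells, rose in R2i against PD by 3.15 log2 units in B18 and 1.08 in B20 (difference -2.07, adjusted p = 2.2e-04). In 2i against PD it was 0.96 higher in B18 and 1.49 log2 units lower in B20 (difference -2.45, adjusted p = 1.9e-04). Dppa3 was not detected on B18 PD replicates 1 and 3 (4.91 and 4.76) or on B20 2i replicate 2 (4.70). Its changes in both comparisons and their differences thus rest in part on background. The imprinted growth factor adaptor gene Grb10 had changes of 1.86 and -0.16 in R2i against PD (difference -2.01, adjusted p = 1.5e-06) and of 1.65 and -0.25 in 2i against PD (difference -1.89, adjusted p = 2.0e-05). For R2i against PD, the calcium-binding protein gene S100a1 had -0.11 in B18 and -2.42 in B20 (difference -2.31, adjusted p = 8.0e-04), the aquaporin gene Aqp3 1.40 and -0.55 (difference -1.94, adjusted p = 3.3e-04) and the germline gene Rhox9 1.41 and -0.50 (difference -1.90, adjusted p = 3.1e-04).

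The glycoprotein gene Gpnmb had changes of -1.05 in B18 and 1.14 in B20 in 2i against PD (difference 2.19, adjusted p = 5.1e-04) and of 1.48 and -0.98 in R2i against 2i (difference -2.46, adjusted p = 2.6e-04). For 2i against PD, the interferon-inducible gene Samd9l had -0.76 and 1.25 (difference 2.01, adjusted p = 3.6e-04) and Lrrc15 0.35 and -1.45 (difference -1.80, adjusted p = 7.9e-04). For R2i against 2i the fatty acid receptor gene Ffar2 had 1.38 and -0.07 (difference -1.44, adjusted p = 0.0028), LOC100046802 0.37 and -1.16 (difference -1.54, adjusted p = 0.0070), the adhesion receptor gene Adgre5 -0.10 and -1.81 (difference -1.71, adjusted p = 0.024) and the G protein gene Gna14 -0.40 and 1.03 (difference 1.43, adjusted p = 0.049). Ffar2 was detected on 4 of 6 R2i and 1 of 4 2i arrays, and Gna14 on 3 of 6 and 2 of 4. The changes and differences of these 2 genes rest in part on background. The call of Adgre5 ended without B18 2i replicate 2 (adjusted p = 0.13), B20 2i replicate 1 (0.11) or B18 R2i replicate 3 (0.051), and that of Gna14 without B18 2i replicate 2 (0.23), B20 2i replicate 1 (0.20) and most other single arrays.

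The first pattern weighed is that the effect of a medium differed between B18 and B20. B20 PD replicate 3 and B20 2i replicate 2 did not produce it, since 124 genes differed for R2i against PD without them, 63 of the 65 among these. A narrower signal range on 1 chip would make nearly all changes smaller in 1 line. B20 had the smaller change in 75.4% of the 65 genes (95% interval 63.1% to 85.2%), which argues against that as the whole cause. The interval treats genes as independent, which they are not. Before normalisation the highest raw signal per array was greater in B20 (28458.6 to 32225.8) than in B18 (22285.5 to 24467.0). Other chip effects and a biological difference between the lines remain open, since each line was on its own chip, and neither was tested.

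The second pattern is that B20 PD replicate 3 lay apart from the other B20 PD arrays. Its signal over background, 2.41, was the highest of the 16 arrays, which argues against weak hybridisation, and its correlation of 0.9925 with the other B20 PD arrays exceeded those with R2i (0.9912) and 2i (0.9875), which argues against an exchanged label. A shift of all its cells part of the way to R2i would need 29.9% of the log2 change from genes lower in R2i (23.5% to 33.3%) but 53.9% from genes higher in R2i (45.8% to 61.3%). Mixing with R2i material may explain the median shift of genes that R2i changed, at 40.1% from 59 genes lower (34.4% to 46.9%) and 40.8% from 39 genes higher (33.8% to 50.2%). No single share covers every such gene. Rhox5 (5.18 against 4.65 and 5.02 in the other B20 PD arrays and at least 7.44 in B20 R2i) stayed near PD. So did Id1 (4.90 against 4.82 and 4.58, and at least 6.52 in R2i) and Dppa3 (6.33 against 6.40 and 6.69, and at least 7.50 in R2i). Mixing does not account for these genes. Nor does it account for Spink1, 1.07 above the other B20 PD arrays though R2i lowered it, or for Fos (12.07 against at most 11.15 in B20 R2i) and Fosb (8.63 against at most 7.93). B20 PD replicate 1 also had Fos and Fosb high (11.52 and 8.19) and replicate 2 low (10.07 and 5.36). The source stays open and no biological explanation was tested.

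Splits of the arrays within each line asked whether chance could give as many calls. For R2i against 2i 1 of 100 splits, the real one, gave 114 or more genes, and the highest of the others gave 9. For R2i against PD 1 of 100, drawn from 200 possible, gave 66 or more (highest other 23). For 2i against PD 1 of 100 gave 77 or more (highest other 20). A chance division of these arrays therefore rarely gives these 3 counts. If the replicates were technical, splits cannot show chance differences between cultures, so these are not excluded. For the difference between the lines in R2i against PD 6 of 100 splits gave 65 or more (highest other 174). The other 5 kept or fully exchanged the B18 media while exchanging B20 arrays, so the effect of the medium in B18 enters them as a difference, a structure of the samples, and this count does not decide whether chance can be excluded. For B18 alone (117 genes) and B20 alone (77 genes) 1 of 10 splits gave as many and the highest other gave 0, and 10 splits are too few for a share under 0.05.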

How the results depend on the processing

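The only alternative chosen after seeing the data was leaving out both B20 PD replicate 3 and B20 2i replicate 2. No called named gene or list changed its direction, while of the named-gene values that had not passed 7 changed sign and 15 came to pass, and median scaling turned the balance of some counts, given below. Calls of named genes kept their direction and call in 3453 cases and lost the call in 380 under the alternatives other than leaving out arrays, in 4643 and 327 with 1 array left out, and in 264 and 11 with both those B20 arrays left out.

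Counts below are in the order R2i against 2i, R2i against PD, 2i against PD. Without background correction, which shrinks changes of weak signals, they were 26, 18 and 15 (B18 alone 32, 26 and 24, B20 alone 39, 20 and 17, differences 2, 12 and 8), and in B4 and C17 4 for R2i against PD, 15 for R2i against SB and 44 for PD against SB. Only genes detected on every array, so fewer genes tested, gave 72, 44 and 40 (B18 alone 94, 77 and 70, B20 alone 95, 51 and 58, differences 21 for R2i against 2i and 28 for 2i against PD), and 9 for R2i against PD in B4 and C17. Without a detection filter the differences were 15 for R2i against 2i and 30 for 2i against PD, and B4 and C17 gave 0, 0 and 2. With no line term B4 and C17 gave 0, 0 and 3, and 3 of 95 named genes. With no minimum fold the counts were 2539, 1732 and 2176, and 242 and 576 for R2i and PD against SB.

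Median scaling gave 51 differences for R2i against 2i (5 higher and 46 lower, against 10 and 22), array weights 98 for R2i against PD, and a replicate block 18 for R2i against 2i. In R2i against PD of B4 and C17, array weights gave 23 genes and only the arrays of the 2 media compared 29. Leaving out both B20 PD replicate 3 and B20 2i replicate 2 gave 172 genes for 2i against PD in B20 alone, and differences of 104, 124 and 130. Except where a construction is named, the cause was not tested. Median scaling also moved splits of higher and lower: R2i against 2i in B18 93 and 57 (from 71 and 82), R2i against PD in B18 31 and 83 (from 44 and 73), 2i against PD 38 and 46 (from 43 and 34), in B18 36 and 96 (from 55 and 66), its difference 57 and 13 (from 31 and 19), and R2i against SB 33 and 66 (from 45 and 47). The median of all genes then shifted by -0.12 in the R2i against 2i difference, -0.14 in 2i against PD in B18 and 0.10 in its difference.

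With single arrays left out, R2i against 2i gave 111 to 131 genes, R2i against PD 62 to 79 and 2i against PD 74 to 85. B18 alone gave 144 to 188, 113 to 125 and 117 to 138, and B20 alone 131 to 214, 61 to 98 and 99 to 144. The differences ranged from 13 (without B20 2i replicate 1) to 83 (without B20 2i replicate 2), 54 to 122 (without B20 PD replicate 3) and 29 (without B18 2i replicate 2) to 95 (without B20 PD replicate 3). In B4 and C17 R2i against PD ranged from 5 (without C17 R2i) to 46 (without B4 R2i), R2i against SB from 46 (without C17 R2i) to 234 (without B4 SB) and PD against SB from 143 (without C17 PD) to 283 (without B4 SB). A medium left with 1 array is assumed to vary like the others.

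Of 138 pairs of list and comparison, camera called 45 with the preset correlation and 1 with an estimated correlation, fry called 40 (21 of the 45 among them), and the deposited normalised table gave 45. Replicates were not treated as paired, as 4 of 16 arrays matched best with their own number in another medium. Signal over background in B4 and C17 (1.32 to 1.38) was taken over all probes, of which 30.0% to 31.7% were detected. It is therefore no measure of how well weakly expressed genes were seen. Changes of genes near background stay uncertain on both platforms.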

Other observations

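The tests of overlap were chosen after the results were seen, and the test of correlations between changes before.

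Dppa3 and Rhox5, which rose in R2i against PD in B18 and B20, had mean log2 levels in B4 and C17 of 10.58 and 10.92 in PD, 11.01 and 11.41 in R2i and 10.53 and 10.51 in SB. In PD they were 5.01 and 5.41 in B18 and 6.47 and 4.95 in B20. Egr1 lay at 10.70 to 12.79 on the B18 and B20 PD arrays. In B4 and C17 it was 5.02 and 4.81 in PD and 9.55 in SB in each line. How far PD blocked MEK was not measured. The platforms were normalised apart, so these levels are not compared by a test.

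The hypothesis tested was that SB and CHIR, each present beside PD, move some of the same genes, as a shared response to a second inhibitor. Changes measured on different arrays were set against each other, so that no PD array was shared. R2i against PD in B18 correlated with 2i against PD in B20 at 0.0584, the reverse at 0.166, and R2i against PD in B4 and C17 with 2i against PD in B18 and B20 at 0.0142, across genes that are not independent replicates. The lowest is below the 0.1 set before the test, so a response shared by most genes was not borne out. A correlation over all genes cannot decide whether a few genes are shared. The same medium correlated between B18 and B20 at 0.486 (R2i against PD) and 0.540 (2i against PD).

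Genes called 2-fold nonetheless overlapped. For R2i against PD in B18 with 2i against PD in B20, 6 genes were higher in both and 6 lower in both, where independent lists would share 0.325 and 0.301, and 6 were opposed. The other way round, 4 were higher and 14 lower in both, where independent lists would share 0.137 and 0.387, and 0 were opposed. Bcas1, Fkbp6 and Rhox5 were higher and Dpysl4, Igfbp7, Sox7 and Spink1 lower in both comparisons of this kind. In R2i against PD of B4 and C17, Rhox5, Dpysl4, Igfbp7 and Spink1 kept these directions in each line. Bcas1 (-0.124 in B4 and -0.233 in C17) and Sox7 (0.556 and 0.175) went the other way there, and Fkbp6 (0.071 and -0.215) was split. Media held the same array positions in both lines, so an effect of position is not set apart from a shared response.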
